A study of Mus musculus with 8 samples.

How the data were processed

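RNA was sequenced from sorted hepatic macrophages of mice in 8 libraries: Kupffer cells and monocyte-derived macrophages (MoM), each from dnTGFβRII (TG) and wild-type (WT) animals, with 2 libraries per group. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, reads were aligned to the mouse genome (mm10, the same assembly as GRCm38) with STAR 2.5.2b. The authors' counter, annotation and strand setting are not given in the sources used here.

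The deposited files for each library hold counts, 1 whole number per gene symbol, with no normalization. Counts below 20 were even in 65.0% to 68.0% of cases, as when the 2 mates of a fragment are counted separately, and 53 genes in 20 groups carried counts identical to those of another gene in all libraries. Such counts overstate the number of independent fragments, and the values of genes within such a group are not separate measurements. Library totals were 26190194 to 30308132 counts, so that 1 count equals 0.0330 to 0.0382 CPM. Of 24786 symbols, 24258 (97.9%) matched GENCODE M21, which supplied the positions. No mitochondrially encoded gene is in the files.

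A further table by the authors lists 179 genes for TG against WT without naming the cell type. Per the file headers, its columns are those of DESeq2: a mean of normalized counts (baseMean, a unit other than a raw count), a log2 fold change with its error, a Wald statistic (a score), and a p-value with its adjusted value. Its baseMean lay within 1% of the mean size-factor-normalized count of the 4 Kupffer libraries for 179 of the 179 genes and of the 4 MoM libraries for 0, so it was set beside the Kupffer comparison.

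All 8 libraries were fitted together with 4 groups in edgeR 4.0.16 (R 4.3.3): filterByExpr on the groups, which left 15254 genes, TMM normalization, and the quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p below 0.05. The common biological coefficient of variation was 0.507, with 4 residual and 2.37 prior degrees of freedom. The 5 comparisons were TG against WT in each subset, MoM against Kupffer cells in each genotype, and the interaction, the TG effect in MoM minus that in Kupffer cells. On simulated data with the spread of these libraries, the fit recovered 0 of 50 genes changed 2-fold, 7 of 50 changed 4-fold and 29 of 50 changed 8-fold in the Kupffer comparison. Levels are given as CPM, edgeR's TMM-scaled counts relative to library size.

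Before the data were examined, 37 gene lists were fixed: 3 of macrophage identity, 20 of functions, 13 of other cell types and 1 of dissociation stress. They hold 633 entries, of which 4 are not in the files and 1 is a repeat. Each was tested with camera of limma 3.58.1, two-sided, with the preset inter-gene correlation of 0.01, adjusted over all lists and comparisons together. Counts of called members are given over all genes and adjusted over the list alone. The genes to be named were also set by a rule beforehand. It takes the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between groups, and up to 3 called members of each called list. Where fewer than 3 genes were called it takes the 5 smallest p in each direction (for the interaction, 5 in all), as values only. Members of lists with the smallest p serve as examples, and Tgfbr2 and 8 subset markers as label checks. Predicted genes and receptor segments were left out, and 1 member of the lists is not reported here on its own.

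The alternatives tried were median-of-ratios size factors, no filter on low counts, the replicate number as a block, each library left out in turn, only the 4 libraries compared, a log2 fold change of at least 1, DESeq2 1.42.0, and camera with an estimated correlation. Added after seeing the data was DESeq2 on only the 4 libraries compared. A fit without both libraries that carry much RNA of other cells (Kupffer TG replicate 2 and MoM WT replicate 1) was also added then. Libraries kept in that fit carried markers of other cells too. In mean log2(CPM + 0.5), neutrophil markers had 6.65 in MoM TG replicate 2 and cholangiocyte markers 3.37 in MoM WT replicate 2, the highest of all libraries. Endothelial markers had 7.64 and 7.62 in these libraries, so that fit is not free of other cells' RNA. Groups of 2 are too small for a test of outlying samples or of other splits of the samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3 and numpy 2.4.6.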

Results

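Messenger RNA of hepatic macrophages was measured in 8 libraries, 2 in each of 4 groups. Kupffer cells, the resident macrophages of the liver, and monocyte-derived macrophages (MoM) came from TG mice, which carry a dominant-negative TGF-β receptor II in T cells and serve as a model of cholangitis, and from WT mice. Libraries held 26190194 to 30308132 counts, and 15366 to 17674 genes had a count. Levels are CPM, given as mean ± SD with n = 2 libraries per group. Log2 fold changes are given with their SE. The labels do not say whether replicates came from separate animals. The p-values of single genes therefore rest on the spread between these libraries, estimated jointly over the 4 groups. Those of gene lists compare the list's genes with all other genes, and measure no spread between animals.

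Tgfbr2, the gene of TGF-β receptor II (chromosome 9, 116084293 to 116175360, GRCm38), stood at similar levels in both genotypes. In Kupffer cells it had 304 ± 20.7 CPM in TG and 347 ± 2.89 CPM in WT (n = 2; log2 fold change -0.19 ± 0.25, adjusted p = 0.887). In MoM it had 214 ± 50.2 CPM in TG and 203 ± 41.1 CPM in WT (log2 fold change 0.07 ± 0.25, adjusted p = 0.972). The sign in MoM turned to -0.18 without TG replicate 1 and to -0.12 without WT replicate 2. Counts per gene do not separate a transgene from the endogenous gene.

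Clec4f, a lectin of Kupffer cells (chromosome 6, 83644542 to 83656187), stood at 11553 and 12314 CPM in the WT Kupffer libraries and at 6558 and 2736 CPM in the TG Kupffer libraries. It stood at 125 and 45.6 CPM in TG MoM and at 33.3 CPM in MoM WT replicate 2, but at 3599 CPM in MoM WT replicate 1. Kdr, a VEGF receptor of endothelial cells, stood at 1107 CPM in Kupffer TG replicate 2 against 17.0 to 60.7 CPM in the other 3 Kupffer libraries. It stood at 946 CPM in MoM WT replicate 1 against 60.3 to 297 CPM in the other 3 MoM libraries. Neutrophil granule genes stood out in MoM TG replicate 2, where Ngp had 1584 CPM and S100a9 had 842 CPM, against at most 32.1 and 28.6 CPM elsewhere. Kupffer TG replicate 2 correlated more closely with MoM WT replicate 1 (Spearman's rho 0.950 across genes, which are not independent replicates) than with Kupffer TG replicate 1 (0.885).

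**Figure D1:**
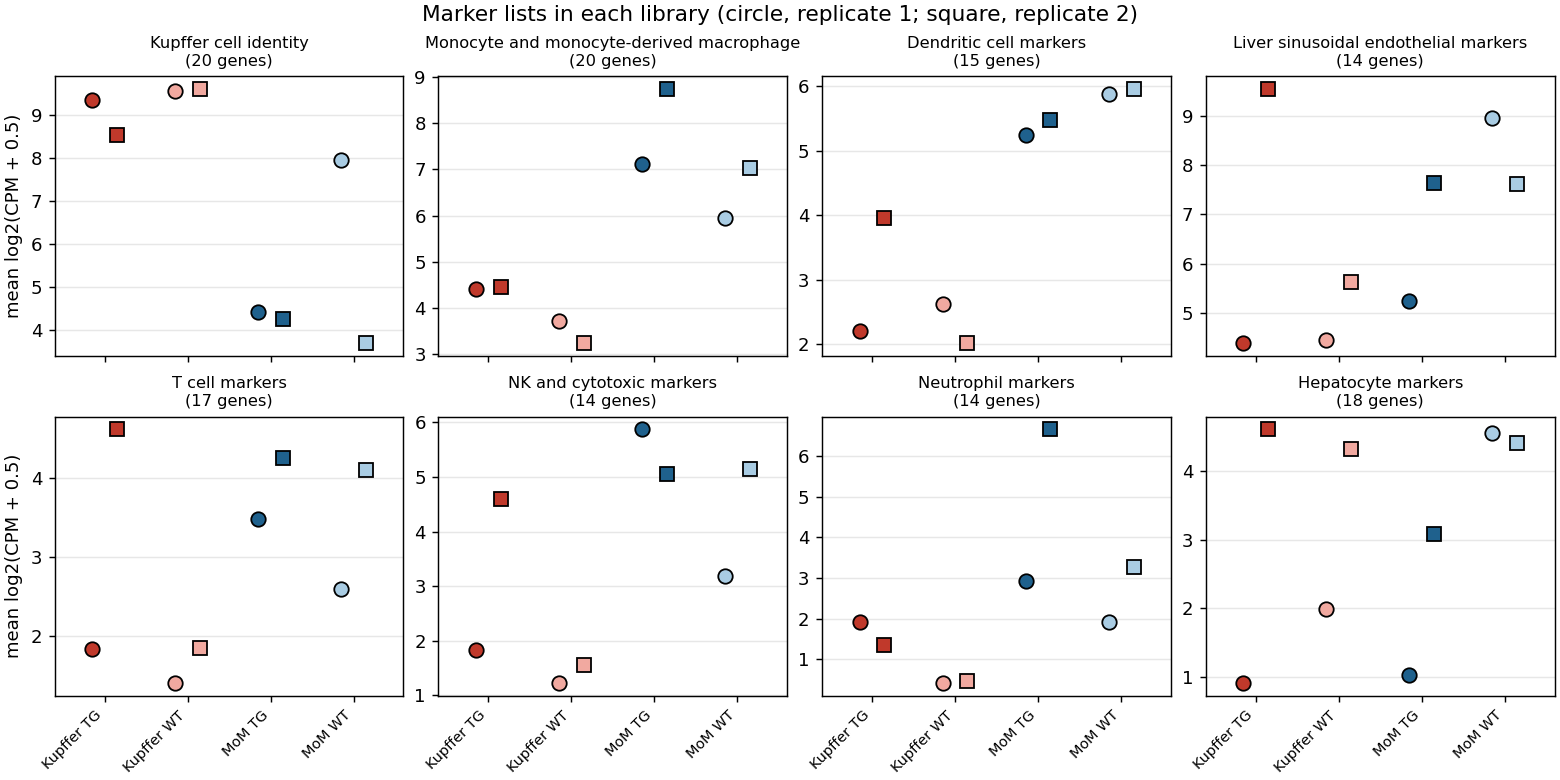
Mean log2(CPM + 0.5) of 8 marker lists in each library (vertical axes, each panel on its own scale), by group on the horizontal axis, with circles for replicate 1 and squares for replicate 2. Kupffer TG replicate 2 and MoM WT replicate 1 lie highest for endothelial markers, with list means of 9.55 and 8.97, and MoM WT replicate 1 lies well above the other MoM libraries for Kupffer cell identity.

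The WT comparison of MoM with Kupffer cells asked what sets the 2 subsets apart in healthy liver. MoM carried far more RNA of many monocyte and dendritic cell genes, though not of all. Mgl2, a galactose-binding lectin of monocyte-derived and dendritic cells (chromosome 11, 70130329 to 70137550), rose from 0.311 ± 0.0174 to 80.6 ± 23.4 CPM (n = 2; 256-fold, adjusted p = 0.00385). Cd209a, a C-type lectin of monocyte-derived dendritic cells (chromosome 8, 3743397 to 3748984), rose from 0.546 ± 0.244 to 254 ± 111 CPM (log2 fold change 8.85 ± 0.74, adjusted p = 0.026). Ccr2, the chemokine receptor that brings monocytes into tissue, rose from 5.17 ± 1.83 to 157 ± 41.4 CPM (log2 fold change 4.92 ± 0.52, adjusted p = 0.026). Ly6c2, another label check, stood at 5.91 ± 5.82 CPM in WT Kupffer cells and at only 29.6 ± 20.1 CPM in WT MoM. In TG MoM it had 33.4 CPM in replicate 1 and 517 CPM in replicate 2, where neutrophil genes stood out. Kupffer genes were lower in MoM as a list (adjusted p = 4.3e-10, or 0.612 with an estimated correlation).

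Of 15254 genes, 178 were called, 169 higher and 9 lower in MoM. The other largest rises were Mmp25, a membrane metalloprotease (45.7 ± 35.1 CPM in MoM), S100a4, a calcium-binding protein of monocytes (212 ± 199 CPM), Flt3, the growth factor receptor of dendritic cells (267 ± 66.3 CPM), Il1r2, the decoy receptor for interleukin 1 (200 ± 180 CPM), Sh2d1b1 (14.3 ± 8.28 CPM) and Ffar2, a receptor for short-chain fatty acids (19.2 ± 10.1 CPM). Each of these 6 had at most 1.35 CPM in WT Kupffer cells. Of the 9 lower genes, 6 met the level and overlap rule: Fmn1 (-2.11 ± 0.23), Ago3 (-2.05 ± 0.31), Cep290 (-1.85 ± 0.27), Zeb2os (-1.74 ± 0.25), Dock4 (-1.53 ± 0.20) and Pgm2l1 (-1.39 ± 0.18), on the log2 scale.

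By list, 23 of 37 were called in WT, 15 up and 8 down, and 18 of these kept their call whichever library was left out. The monocyte list rose (20 genes, median log2 3.09, adjusted p = 8.1e-09), with 4 members called over all genes and 16 adjusted over the list alone, 15 of them up. Its called members with the smallest p were Napsa, an aspartic protease (7.29 ± 0.77), Ccr2 and S100a6 (6.37 ± 0.88). The dendritic cell list rose (15 genes, median 4.14, adjusted p = 5.1e-11; 6 called), with Itgax, the integrin CD11c (5.05 ± 0.64), and Kmo (5.22 ± 0.71). The MHC class II list rose (12 genes, median 1.55, adjusted p = 4.1e-07; 3 called, 9 up adjusted over the list alone). Its called members were H2-Oa (123 ± 57.9 CPM in MoM and 1.36 ± 0.0889 CPM in Kupffer cells), H2-Ob (4.85 ± 0.54) and H2-DMb2 (2.81 ± 0.36), which load or edit peptides on MHC class II. The costimulation list was called through Pdcd1lg2, a checkpoint ligand (2.45 ± 0.33), and Icosl (2.47 ± 0.36), at adjusted p = 0.0225, which became 0.178 without Kupffer WT replicate 2 and 0.0768 without MoM WT replicate 2. All 22 genes for cytosolic ribosomal proteins were higher (median 0.94, adjusted p = 2.4e-07), among them Rps16 (1.17 ± 0.18, called). Cell cycle genes rose too (25 of 26 positive, median 1.00, adjusted p = 7.6e-05). With an estimated correlation between genes none of these lists was called (adjusted p = 0.612 to 0.721), and no list was called in any comparison.

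Lower in WT MoM as lists were Kupffer cell identity (20 of 20 genes negative, median -2.67, adjusted p = 4.3e-10), lysosome (22 of 22, median -1.04, adjusted p = 8.0e-10; 17 down adjusted over the list alone, 0 over all genes), pan-macrophage genes (median -1.55, adjusted p = 5.7e-07), iron and heme handling (median -1.79, adjusted p = 1.8e-06), targets of the sterol receptor LXR (median -1.52, adjusted p = 8.5e-06), the type I interferon response (median -0.87, adjusted p = 8.9e-06) and complement and Fc receptors (median -1.75, adjusted p = 0.00061). Each lost its call with an estimated correlation (adjusted p = 0.612 to 0.631). Single Kupffer markers, though not Cd68, had wide errors in WT, since MoM WT replicate 1 carried Kupffer genes at a median of 30.9% of their WT Kupffer level. Clec4f had a log2 fold change of -2.72 ± 1.70 (adjusted p = 0.333), Timd4, a phosphatidylserine receptor, -2.69 ± 1.29 (0.238), Vsig4, a complement receptor, -2.79 ± 1.34 (0.237), Adgre1, which encodes F4/80, -2.47 ± 0.74 (0.126), and Cd68 -1.45 ± 0.30 (0.0745). Beside the rise in monocyte genes, markers of other cells were also higher in WT MoM. Medians were 6.29 for cholangiocyte, 6.54 for mast cell and basophil, 4.10 for B cell, 3.85 for neutrophil and 3.49 for NK markers. Endothelial markers had a median of 3.82 (adjusted p = 0.00245) and T cell markers 2.43 (adjusted p = 0.00646). With an estimated correlation these lists had adjusted p = 0.612 to 0.721. The endothelial call ended without MoM WT replicate 1, and the T cell call without MoM WT replicate 2. Cholangiocyte markers had a list mean (log2) of 3.37 in MoM WT replicate 2 and 1.12 in replicate 1. Mast cell and basophil markers had 4.03 and 1.63, so both sizes leaned on replicate 2. In WT Kupffer cells cholangiocyte markers had -0.80 and -0.51 and mast cell and basophil markers -0.37 and -0.078, near the lowest countable level. The sizes of these medians are therefore uncertain.

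The number of called genes in WT depended on single libraries. It was 1378 without Kupffer TG replicate 1, 1434 without Kupffer TG replicate 2, 729 without MoM WT replicate 1 (391 higher, 338 lower), 0 without either Kupffer WT library, and 1 without either MoM TG library or without MoM WT replicate 2. It was 2677 without both libraries rich in other cells' RNA (1510 higher, 1167 lower) and 2867 with DESeq2 (1815 higher, 1052 lower), and both sets contained all 178 genes.

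**Figure D2:**
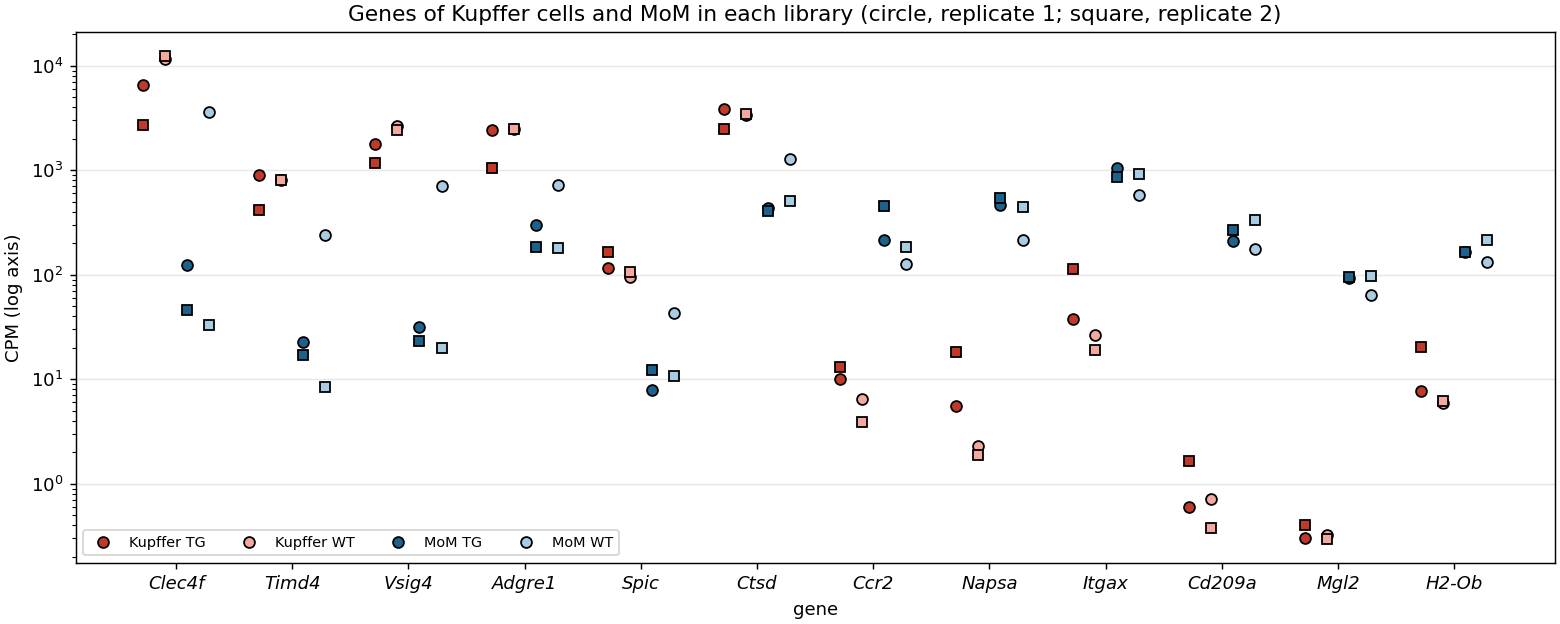
CPM on a log axis of 12 genes in each library, coloured by group, with circles for replicate 1 and squares for replicate 2. The 6 Kupffer genes on the left are lower in every MoM than in every Kupffer library, except for Clec4f in MoM WT replicate 1. Clec4f had 3599 CPM there, against 33.3 CPM in MoM WT replicate 2 and 2736 CPM in Kupffer TG replicate 2. The 6 MoM genes on the right are separated in every library.

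The TG comparison of MoM with Kupffer cells asked the same of diseased liver. Mgl2 rose from 0.354 ± 0.0729 to 94.5 ± 1.81 CPM (n = 2; log2 fold change 8.04 ± 0.35, adjusted p = 0.00367) and Cd209a from 1.13 ± 0.746 to 238 ± 40.7 CPM (7.71 ± 0.70, adjusted p = 0.0188). Ace, the angiotensin-converting enzyme, rose from 8.81 ± 1.61 to 877 ± 534 CPM (6.64 ± 0.60, adjusted p = 0.0188). Igf1, the growth factor, fell from 379 ± 145 CPM in Kupffer cells to 7.41 ± 0.169 CPM in MoM (-5.68 ± 1.03, adjusted p = 0.0493), and Spic, the transcription factor of iron-recycling macrophages, from 140 ± 35.3 to 10.1 ± 3.02 CPM (-3.79 ± 0.68, adjusted p = 0.0486).

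In all, 381 genes were called in TG, 281 higher and 100 lower in MoM. Of those called higher, 121 were also among the 169 called higher in WT, and of those called lower, 2 were among the 9 called lower in WT. Independent lists would share 3.11 and 0.059. Both comparisons came from 1 fit with a shared estimate of the spread, so these expected numbers do not gauge the overlap. The other largest rises were Ffar2 (a mean of 51.6 CPM in MoM and 0.148 CPM in Kupffer cells), Serpinb10 (7.59 ± 0.90), Ctnnd2 (7.48 ± 0.86), Gpr141 (6.55 ± 0.80) and Il1r2 (6.34 ± 0.96). The other largest falls were Adam33 (-5.23 ± 0.74), Pdgfc, a growth factor (-5.11 ± 0.69), Sdc2 (-4.77 ± 0.57), Hey1, a Notch target (-4.64 ± 0.76), Fblim1 (-4.46 ± 0.80), Stard13 (-4.41 ± 0.58) and Ephx1, an epoxide hydrolase (-4.09 ± 0.62).

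By list, 23 were called in TG, 11 up and 12 down, and 16 kept their call whichever library was left out. Kupffer cell identity fell (20 of 20 negative, median -5.18, adjusted p = 1.9e-13), with 1 member called over all genes and 19 adjusted over the list alone. The monocyte list rose (median 4.02, adjusted p = 6.9e-13; 3 called, 18 adjusted over the list alone), with Ccr2 (4.86 ± 0.51), Napsa (5.41 ± 0.70) and Ms4a4c (4.60 ± 0.73). Dendritic cell markers rose (median 1.33, adjusted p = 1.9e-05), with Kmo (6.19 ± 0.74) and Itgax (3.64 ± 0.60). Cell cycle genes rose (26 of 26 positive, median 1.25, adjusted p = 5.3e-10), with Mcm5 (1.23 ± 0.19), Mcm7 (1.26 ± 0.19) and Rrm2 (1.74 ± 0.28), which serve DNA replication. The costimulation list rose (median 1.06, adjusted p = 0.0069), with Havcr2, the checkpoint receptor TIM-3 (4.33 ± 0.55), Icosl (2.73 ± 0.36) and Tnfsf13b (2.53 ± 0.45). Ribosomal protein genes rose (22 of 22 positive, median 0.91, adjusted p = 1.4e-07). Lower lists included iron and heme handling (median -1.89, adjusted p = 5.7e-07; Slc48a1, a heme transporter, -1.89 ± 0.32, Ncoa4, the receptor for ferritin breakdown, -2.42 ± 0.41), lysosome (median -1.05, adjusted p = 1.5e-07; Ctsd, cathepsin D, -2.90 ± 0.52) and complement and Fc receptors (median -1.55, adjusted p = 0.00074; C3ar1, the C3a receptor, -2.79 ± 0.33). The genes for clearance of dead cells and C1q also fell (median -2.09, adjusted p = 4.1e-05), and so did the interferon gamma response (median -0.75, adjusted p = 0.0023) and the type I interferon response (median -0.74, adjusted p = 0.00021). All of these lists lost their call with an estimated correlation (adjusted p = 0.612 to 0.653).

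In TG, neutrophil markers (median 5.11, adjusted p = 0.00018) and mast cell and basophil markers (median 4.15, adjusted p = 0.00055) moved with the monocyte genes (both adjusted p = 0.612 to 0.631 with an estimated correlation). The size of the neutrophil rise rested largely on MoM TG replicate 2. The list mean (log2) was 6.65 there and 2.91 in MoM TG replicate 1, against 1.91 and 1.35 in TG Kupffer cells. MHC class II genes were less far apart than in WT: the list had a median of 0.25 (adjusted p = 0.0323, or 0.637 with an estimated correlation), with H2-Oa (4.07 ± 0.61), H2-Ob (3.54 ± 0.51) and H2-DMb2 (2.01 ± 0.34) called. That list call ended without Kupffer TG replicate 2 (adjusted p = 0.231), Kupffer WT replicate 1 (0.0545) or 2 (0.0595), or MoM TG replicate 1 (0.0677). The chemokine list (median -1.01, adjusted p = 0.0323, or 0.677 with an estimated correlation) held the called genes Ccl12 (-3.54 ± 0.50) and Pf4 (-2.76 ± 0.44). Its call ended without Kupffer TG replicate 2 (0.417) or MoM TG replicate 1 (0.278). Srebf2, the regulator of cholesterol synthesis, rose (1.89 ± 0.29), in a list called at adjusted p = 0.0448 (0.677 with an estimated correlation), which became 0.54 without Kupffer TG replicate 2, 0.181 without MoM TG replicate 1 and 0.0519 with size factors. Label checks not called were Clec4f (-5.77 ± 1.96, adjusted p = 0.136), Vsig4 (-5.74 ± 1.53, 0.0902) and Itgam, the integrin CD11b (3.46 ± 0.66, 0.0544).

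The number of called genes in TG was 0 without Kupffer TG replicate 1 and 850 without Kupffer TG replicate 2. It was 1006 without MoM WT replicate 1 (490 higher, 516 lower), 1026 without MoM WT replicate 2, and 1 without any one of the Kupffer WT or MoM TG libraries. It was 0 when only these 4 libraries were fitted, 2130 without both libraries rich in other cells' RNA (1021 higher and 1109 lower, 345 of the 381 among them), and 2563 with DESeq2 (1265 higher and 1298 lower, all 381 among them). The excess of higher over lower genes held without Kupffer TG replicate 2. It did not hold without MoM WT replicate 1, without MoM WT replicate 2, without both libraries rich in other cells' RNA or with DESeq2.

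The comparison of TG with WT Kupffer cells asked how the disease model alters resident macrophages. Genes induced by interferon gamma and genes of MHC class II were higher in TG. Gbp4, an interferon-induced GTPase (chromosome 5, 105115767 to 105139586), stood at 463 ± 35.5 CPM in TG and 126 ± 0.308 CPM in WT (n = 2; log2 fold change 1.88 ± 0.31, adjusted p = 0.660). H2-Aa, the MHC class II alpha chain (chromosome 17, 34282744 to 34287823), stood at 4749 ± 151 CPM in TG and 1532 ± 34.0 CPM in WT (1.63 ± 0.39, adjusted p = 0.730). No single gene passed the test in edgeR.

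The interferon gamma list rose in TG Kupffer cells: 26 of its 26 genes were positive, with a median log2 fold change of 1.42 (adjusted p = 6.3e-24). The test with an estimated correlation gave adjusted p = 0.612. Adjusted over the list alone, 16 of the 26 genes passed, against 0 over all genes. In 23 of them both TG libraries lay above both WT libraries, an order that chance gives to 16.7% of genes. Among the smallest p were Gbp5 (1.56 ± 0.28; 195 ± 22.7 CPM in TG and 66.0 ± 7.05 CPM in WT), Tgtp2 (1.53 ± 0.29) and Tgtp1 (1.87 ± 0.35), GTPases that act on intracellular microbes. The MHC class II list rose as well (11 of 12 genes positive, median 1.21, adjusted p = 9.9e-12; adjusted p = 0.612 with an estimated correlation; 6 adjusted over the list alone). Its smallest p after H2-Oa (2.64 ± 0.59) were H2-Aa, H2-Eb1 (1.61 ± 0.39; 3746 ± 1253 CPM in TG and 1231 ± 59.1 CPM in WT) and H2-Ab1 (1.37 ± 0.39). Both lists kept their call whichever library was left out, and without both libraries rich in other cells' RNA. The fits without TG replicate 2 rest on a single TG Kupffer library, replicate 1.

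Markers of other cells rose in the same comparison, and 5 of these lists lost their call without TG replicate 2. Endothelial markers had a median of 3.79 (14 genes, adjusted p = 3.2e-05, or 0.637 with an estimated correlation), with Dnase1l3 (3.53 ± 1.02) and Eng, endoglin (4.03 ± 1.69), and turned to a negative direction without TG replicate 2 (adjusted p = 0.13). T cell markers had a median of 2.66 (adjusted p = 1.1e-07, or 0.612 with an estimated correlation) and were not called without TG replicate 2 (0.2). The same holds for cholangiocyte markers (median 3.18, adjusted p = 0.00044 and 0.612; 0.507 without it) and mast cell and basophil markers (median 5.61, adjusted p = 4.0e-05 and 0.612; 0.0831 without it). Dendritic cell markers (median 0.72, adjusted p = 0.00206 and 0.631) were not called without TG replicate 2 (0.756) or WT replicate 2 (0.145). NK and cytotoxic markers (median 2.99, adjusted p = 1.0e-06, or 0.612 with an estimated correlation) and plasma cell markers (median 1.26, adjusted p = 0.00324, or 0.612) kept their call in every fit with 1 library left out, but their size rested largely on TG replicate 2. NK markers had a list mean (log2) of 4.60 there, 1.83 in TG replicate 1 and 1.23 and 1.55 in WT, and plasma cell markers had 3.12, 2.30, 1.87 and 1.63. In WT, cholangiocyte markers had -0.80 and -0.51 and mast cell and basophil markers -0.37 and -0.078, near the lowest countable level. The sizes of their medians are therefore uncertain. Neutrophil markers (median 3.13, adjusted p = 4.7e-05, or 0.612 with an estimated correlation) were not called without TG replicate 1 (0.148), and B cell markers (median 2.18, adjusted p = 0.00278, or 0.631) not without WT replicate 1 (0.0669). Gzmb, granzyme B, stood at 9.11 and 151 CPM in TG against 2.30 and 3.14 CPM in WT.

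Kupffer cell identity genes were lower in TG by a median of -0.37 (16 of 20 negative, adjusted p = 0.0487, or 0.803 with an estimated correlation). The call ended without TG replicate 2 (adjusted p = 0.77) or WT replicate 1 (0.0553). Its members did not move together: Marco, a scavenger receptor (chromosome 1, 120474538 to 120505024), stood at 4401 ± 1544 CPM in TG and 715 ± 39.9 CPM in WT (2.62 ± 1.38), and Cd209f at 0.602 ± 0.539 and 34.5 ± 5.19 CPM (-5.83 ± 1.58; both adjusted p = 0.730). Cd163, the hemoglobin scavenger receptor, stood at 737 ± 427 and 2291 ± 164 CPM (-1.64 ± 1.40, adjusted p = 0.819). The monocyte list rose (median 1.25, adjusted p = 0.000251, or 0.612 with an estimated correlation), with Napsa (11.9 ± 8.92 CPM in TG and 2.10 ± 0.279 CPM in WT) and S100a6 (2.48 ± 0.76), and was not called without TG replicate 1 (adjusted p = 0.0584). In all, 23 lists were called in this comparison, 18 up and 5 down, of which 19 lost their call without at least 1 library and 23 lost it with an estimated correlation (adjusted p = 0.612 to 0.803).

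The genes with the smallest p in TG Kupffer cells were, on the higher side, Anpep, an aminopeptidase (2.82 ± 0.27; 7.04-fold above the WT level of 7.09 ± 0.634 CPM), Il12rb1, a receptor chain for interleukins 12 and 23 (3.54 ± 0.35; 17.7 ± 3.77 and 1.52 ± 0.119 CPM), Sort1, sortilin (4.28 ± 0.44; 55.0 ± 18.5 and 2.82 ± 1.09 CPM), Gpnmb, a glycoprotein of lipid-laden macrophages (2.59 ± 0.27; 18.6 ± 1.44 and 3.07 ± 0.537 CPM) and Pdcd1lg2 (2.79 ± 0.33; 12.7 ± 0.514 and 1.84 ± 0.361 CPM). The first 4 had adjusted p = 0.199 in edgeR and Pdcd1lg2 had 0.348. On the lower side they were Kntc1 (-1.54 ± 0.24, adjusted p = 0.660), Mxi1 (-0.98 ± 0.19, 0.674), Pf4, platelet factor 4 (-2.30 ± 0.42, 0.674), Wdfy1 (-1.11 ± 0.23, 0.730) and Pola1, a DNA polymerase subunit (-0.98 ± 0.22, 0.730). edgeR called 0 genes, with 906 at an unadjusted p below 0.05 against 762.7 expected by chance. DESeq2 called 251 on all libraries (232 higher, 19 lower) and 185 on the 4 Kupffer libraries. Without TG replicate 1, edgeR called 257 genes, 255 of them higher.

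**Figure D3:**
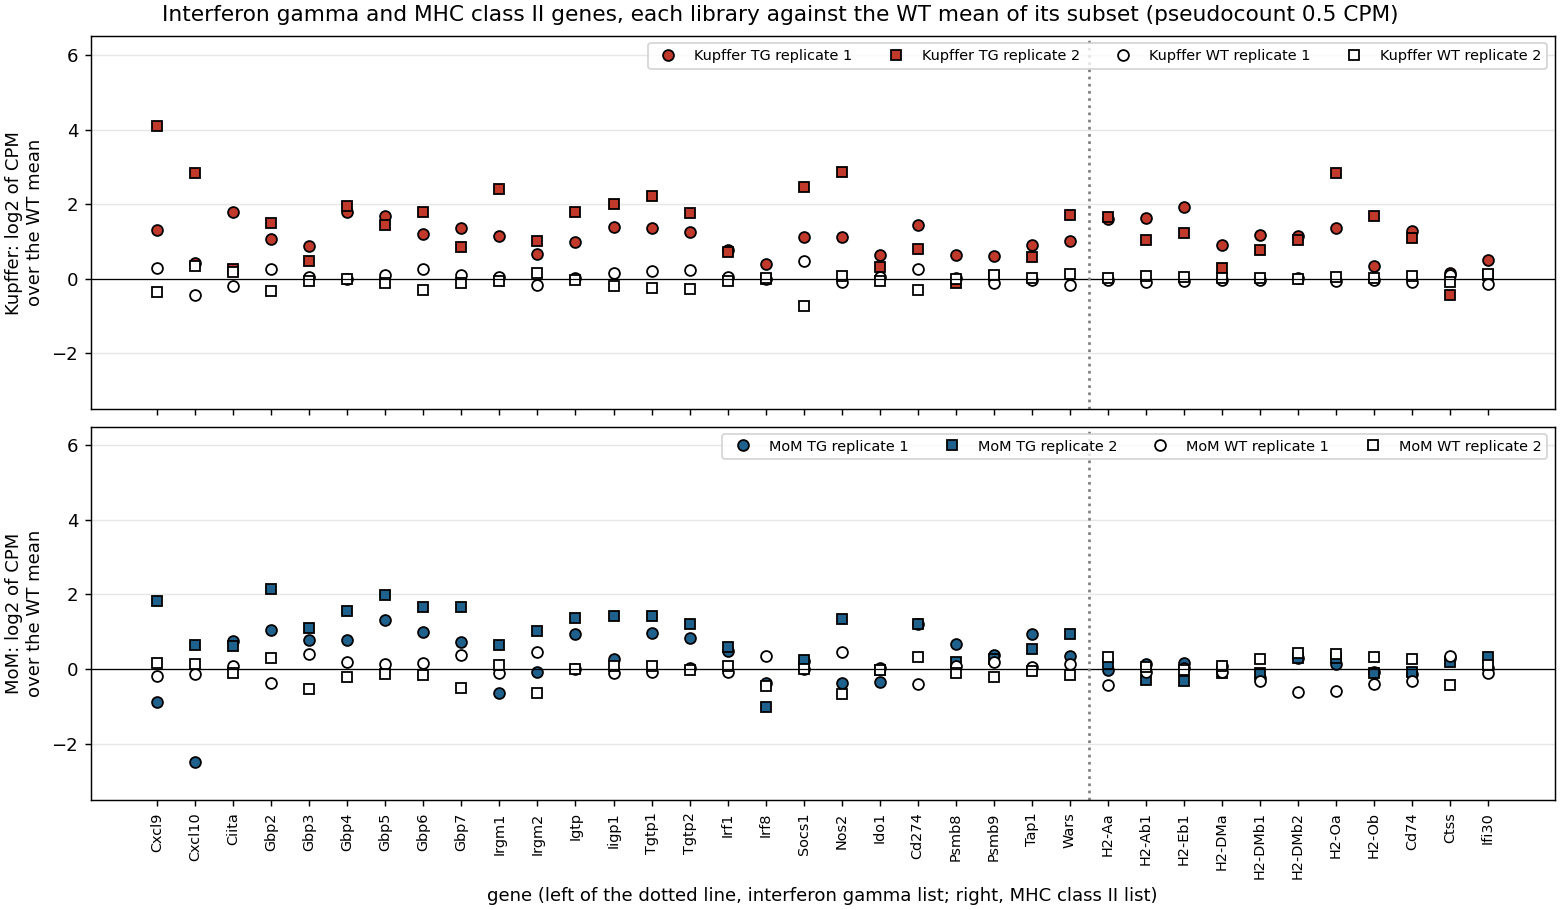
Log2 ratio of each library's CPM to the WT mean of its own subset (vertical axis, pseudocount 0.5 CPM) for the interferon gamma genes and, right of the dotted line, the MHC class II genes, with Kupffer cells above and MoM below; filled symbols are TG and open symbols WT. Of the 26 interferon gamma genes 1 is not drawn, and a gene in both lists is drawn once; in Kupffer TG replicate 1 every gene drawn lies above both WT libraries, while the MHC class II genes of MoM lie about 0.

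The deposited table of 179 genes, 151 higher and 28 lower in TG, shared 174 genes with the 185 that DESeq2 called here on the 4 Kupffer libraries. Every gene of the deposited table had a log2 fold change of at least 1 in size, while the 185 were called without a fold threshold. Among the 151 higher genes, TG replicate 2 lay above both WT libraries in 151 and TG replicate 1 in 139. The median log2 ratio to the WT mean was 1.36 in TG replicate 1 and 2.84 in TG replicate 2, and 45 of the 151 genes were less than 2 times the WT mean in replicate 1. The 28 lower genes lay below both WT libraries in both replicates. In the table, 11 genes belong to a list of another cell type. These lists hold few markers of each cell type, so the count does not measure how many of the 179 genes reflect other cells. The smallest adjusted p that edgeR gave any of the 179 genes was 0.199.

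The comparison of TG with WT MoM asked the same of monocyte-derived cells. Interferon gamma and MHC class I genes were higher in TG. Gbp5 (chromosome 3, 142493978 to 142522344) stood at 107 ± 35.7 CPM in TG and 33.0 ± 4.28 CPM in WT (n = 2; log2 fold change 1.70 ± 0.28, adjusted p = 0.618). Nlrc5, the transactivator of MHC class I genes (chromosome 8, 94434356 to 94527272), stood at 302 ± 5.52 and 132 ± 4.29 CPM (1.19 ± 0.20, adjusted p = 0.618). No single gene passed the test in edgeR.

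The interferon gamma list rose in TG MoM (23 of 26 genes positive, median 0.94, adjusted p = 1.2e-12), and 9 genes passed adjusted over the list alone against 0 over all genes. In 19 of the 26, both TG libraries lay above both WT libraries, where chance gives 16.7%. The MHC class I list rose (16 of 16 positive, median 0.45, adjusted p = 1.3e-05), with Tap1, a peptide transporter (0.75 ± 0.24). Glycolysis genes rose (14 of 16 positive, median 0.36, adjusted p = 0.00086), with Slc2a1, a glucose transporter (1.18 ± 0.33), and Pkm (0.53 ± 0.25). The monocyte list rose (20 of 20 positive, median 1.10, adjusted p = 2.9e-09). Its smallest p were Plac8 (1.56 ± 0.36; 813 ± 93.6 and 276 ± 24.9 CPM), Vcan, versican (6.80 ± 1.81; 110 ± 143 and 0.984 ± 0.519 CPM) and Chil3, a secreted lectin of monocytes and neutrophils (5.59 ± 1.93; 508 ± 700 and 10.6 ± 1.64 CPM). Chil3 stood high in TG replicate 2 alone, with 1003 CPM against 13.3 CPM in TG replicate 1, and its log2 fold change was 0.33 without replicate 2; that of Vcan was 3.15. All 4 lists lost their call with an estimated correlation (adjusted p = 0.612) and kept it whichever library was left out.

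Neutrophil markers rose with the monocyte list (median 4.26, adjusted p = 6.0e-08, or 0.612 with an estimated correlation), with Csf3r, the G-CSF receptor (1.77 ± 0.37), and S100a9 (5.12 ± 1.54), and were not called without TG replicate 2 (adjusted p = 0.0785). Hepatocyte markers fell (17 of 18 negative, median -2.51, adjusted p = 1.2e-07, or 0.612 with an estimated correlation) and kept their call whichever library was left out. Alb, albumin, stood at 8.21 and 134 CPM in TG and at 407 and 445 CPM in WT. Endothelial markers fell (14 of 14 negative, median -1.66, adjusted p = 0.000956, or 0.671 with an estimated correlation), but not without TG replicate 1 (0.146) or WT replicate 1 (0.0795). Kupffer cell identity genes were lower in TG (20 of 20 negative, median -2.85, adjusted p = 3.8e-07, or 0.631 with an estimated correlation). Without WT replicate 1, which leaves a single WT MoM library, their direction turned to higher in TG. Cd163 went from -4.28 to 0.24 and Vsig4 from -3.74 to 0.47 on the log2 scale. The list of dead cell clearance and C1q fell (median -1.37, adjusted p = 0.00039, or 0.612 with an estimated correlation) and also turned without WT replicate 1 (0.749). Dendritic cell markers were not called as a list (adjusted p = 0.089); the smallest p among them belonged to Clec9a (40.4 ± 1.49 CPM in TG and 96.9 ± 33.2 CPM in WT) and Xcr1 (8.82 ± 5.98 and 58.3 ± 9.52 CPM), while Itgae overlapped (78.8 and 59.8 CPM in TG, 103 and 49.9 CPM in WT).

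The genes with the smallest p in TG MoM were, besides Gbp5 and Nlrc5, Ms4a4a, a membrane protein of macrophages (2.74 ± 0.39; 89.4 ± 41.7 CPM in TG and 13.4 ± 3.73 CPM in WT), Smpdl3b, a lipid-modifying enzyme (2.73 ± 0.44; 159 ± 75.8 and 24.0 ± 4.91 CPM) and Fbxl5, an iron-sensing ligase subunit (1.14 ± 0.19; 105 ± 4.59 and 47.8 ± 2.96 CPM). On the lower side they were Nuak1 (-1.74 ± 0.27), Zfp395 (-1.34 ± 0.23), Aldh1l1 (-2.21 ± 0.41), C3ar1 (-1.71 ± 0.32) and Slc22a23 (-2.68 ± 0.51). All 8 of these had adjusted p = 0.618 in edgeR. Each of the lower genes stood higher in WT Kupffer cells than in every MoM library. Each also stood higher in MoM WT replicate 1, which carried Kupffer genes, than in replicate 2. C3ar1 had 177 and 182 CPM in WT Kupffer cells, and 62.7 and 32.4 CPM in MoM WT replicates 1 and 2. In TG MoM it had 15.5 and 13.5 CPM. At each gene MoM WT replicate 2 still lay above both TG libraries. How much of each difference Kupffer RNA accounts for was not tested. edgeR called 0 genes, with 987 at an unadjusted p below 0.05. DESeq2 called 141 on all libraries (67 higher, 74 lower) and 222 on the 4 MoM libraries. Of the 37 lists, 18 were called, 9 up and 9 down, and 5 kept their call whichever library was left out. With an estimated correlation 0 were called (adjusted p = 0.612 to 0.772 for these 18).

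The interaction asked whether the genotype moved the subsets differently. The rise of MHC class II genes was larger in Kupffer cells than in MoM: the list's median was -1.22 (11 of 12 genes negative, adjusted p = 4.7e-05, or 0.612 with an estimated correlation). In MoM, H2-Aa stood at 5636 ± 399 CPM in TG and 5407 ± 1993 CPM in WT, close to the TG Kupffer level of 4749 ± 151 CPM. The call ended without Kupffer TG replicate 1 (adjusted p = 0.0973). Chemokine genes also moved apart (18 of 20 negative, median -1.52, adjusted p = 0.00015, or 0.612 with an estimated correlation). In Kupffer cells the list mean (log2) stood higher in TG replicate 2 alone, at 6.58 against 5.36 in TG replicate 1 and 5.35 and 5.27 in WT. Ccl7 overlapped there, with 37.8 and 91.9 CPM in TG and 54.2 and 15.8 CPM in WT, and stood at 2.89 ± 2.59 and 18.6 ± 7.01 CPM in TG and WT MoM. The largest medians belonged to cholangiocyte markers (-5.87, adjusted p = 6.8e-06, or 0.612 with an estimated correlation) and endothelial markers (-5.48, adjusted p = 1.8e-07, or 0.612 with an estimated correlation). The sizes of both rested largely on single libraries, though the calls stayed with any 1 library left out. Endothelial markers had a list mean of 9.55 in Kupffer TG replicate 2 against 4.39 in replicate 1, and adjusted p = 0.416 without both libraries rich in other cells' RNA. Cholangiocyte markers had 3.37 in MoM WT replicate 2 against 1.12 in replicate 1. In Kupffer cells they had -0.63 and 0.98 in TG and -0.80 and -0.51 in WT, mostly near the lowest countable level. The size of their median is therefore uncertain. For the interferon gamma list the difference was not called (median -0.39, adjusted p = 0.061). The median of all genes lay at -0.12 in this comparison, at 0.11 in WT MoM against Kupffer cells, and within 0.05 of 0 in the other 3.

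No gene was called for the interaction in edgeR, with 980 at an unadjusted p below 0.05, while DESeq2 called 47, and edgeR called 83 without Kupffer TG replicate 1. The 5 smallest p belonged to Htra1, a serine protease (-5.97 ± 0.74), Anpep (-2.80 ± 0.36), Smpdl3b (3.83 ± 0.61), Kntc1 (2.09 ± 0.34) and Hvcn1, a proton channel (-2.14 ± 0.36), all with adjusted p = 0.626. Htra1 stood at 10.2 ± 4.83 CPM in TG and 0.972 ± 0.104 CPM in WT Kupffer cells, and at 1.33 ± 0.384 and 7.95 ± 2.47 CPM in MoM. Anpep stood at a mean of 116 CPM in TG MoM and at 114 ± 13.2 CPM in WT MoM. In all, 14 lists were called, 1 up and 13 down, and 3 kept their call whichever library was left out. With an estimated correlation 0 were called (adjusted p = 0.612 to 0.772 for these 14). Across genes, the genotype effects of the subsets had the same sign in 46.0% of 15254 genes. The libraries rich in endothelial markers, Kupffer TG replicate 2 and MoM WT replicate 1, lie on opposite genotype sides. How far other cells' RNA lowered this share was not tested.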

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

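All tests in this part were chosen after the results were seen. The patterns weighed are the markers of other liver cells in Kupffer TG replicate 2, the rise of interferon gamma and MHC class II genes in TG Kupffer cells, and the lower Kupffer identity genes in TG MoM.

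Endothelial markers such as Kdr and Eng stood at 1107 and 1486 CPM in Kupffer TG replicate 2, against 17.8 and 37.5 CPM in replicate 1. RNA of other liver cells in this library is a candidate explanation: Kupffer identity genes lay lower in replicate 2 than in replicate 1 at 18 of 20 genes, by a median log2 of -0.98, as dilution would give. Higher expression by TG Kupffer cells themselves would raise the markers in both replicates, but replicate 1 lay above both WT libraries at only 2 of 14 markers. Replicate 2 lay below all 4 MoM libraries at 25 of 35 monocyte and dendritic cell genes, which speaks against an exchange of labels with a MoM library. That share only narrowly passed the limit, which was set after the values were seen. How such RNA came into the library was not tested.

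Interferon gamma and MHC class II genes such as Gbp4 and H2-Aa were higher in both TG Kupffer libraries. RNA of other cells in replicate 2 did not account for this, since without that library the larger adjusted p of the 2 lists was 8.1e-19. Dendritic cells in replicate 1 did not account for it either: the median dendritic cell marker exceeded WT by 0.201% of the MoM level, while the MHC class II excess equalled 55.8%. With median-of-ratios size factors as the scaling, the lists had adjusted p = 7.6e-25 and 2.0e-11. The source of the rise stays open, and with an estimated correlation between genes the lists had adjusted p = 0.612.

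Kupffer identity genes such as Clec4f and Vsig4 were lower in TG than in WT MoM. Kupffer cell RNA in MoM WT replicate 1 is the likely source. In that library 37 genes outside the list stood at nearly 1 share of their WT Kupffer level (median 29.8%, ratio of upper to lower quartile 1.30), and the list itself stood at 30.9%, against 1.03% in MoM WT replicate 2. Lower expression in TG MoM did not account for the levels, since both TG libraries lay below MoM WT replicate 2 at only 2 of the 20 genes. Without MoM WT replicate 1 the direction of the list turned to higher in TG, with Clec4f at 1.36 and Vsig4 at 0.47 on the log2 scale. That fit rests on a single WT MoM library.

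In the interaction, 14 lists were called; medians are log2, and each adjusted p that ended or turned a call is given with the library left out. Kupffer cell identity had -2.50 (adjusted p = 0.0105), or 0.659 without Kupffer TG replicate 1, 0.12 without MoM TG replicate 2, 1.5e-07 without MoM WT replicate 1 with the direction turned. MHC class II had -1.22 (adjusted p = 4.7e-05), or 0.0973 without Kupffer TG replicate 1. Chemokines had -1.52 (adjusted p = 0.00015). Lipid-associated macrophage genes had -1.13 (adjusted p = 0.0104), or 0.0583 without Kupffer WT replicate 2, 0.0906 without MoM TG replicate 2, 0.283 without MoM WT replicate 1. Dead cell clearance and C1q had -1.91 (adjusted p = 0.00755), or 0.632 without MoM WT replicate 1 with the direction turned. Cell cycle genes had 0.27 (adjusted p = 0.00564), or 0.183 without Kupffer TG replicate 1, 0.082 without Kupffer WT replicate 2, 0.156 without MoM WT replicate 1. Oxidative phosphorylation had -0.36 (adjusted p = 0.0499), or 0.595 without Kupffer TG replicate 1 with the direction turned, 0.252 without Kupffer WT replicate 2, 0.169 without MoM TG replicate 2, 0.217 without MoM WT replicate 1, and 0.0567 with size factors. T cell markers had -2.13 (adjusted p = 0.0131), or 0.382 without Kupffer TG replicate 2 with the direction turned, 0.0807 without Kupffer WT replicate 1, 0.0576 without MoM TG replicate 1, 0.661 without MoM WT replicate 2. B cell markers had -2.19 (adjusted p = 0.0110), or 0.0759 without Kupffer WT replicate 1, 0.455 without MoM TG replicate 2, 0.0811 without MoM WT replicate 2. Dendritic cell markers had -1.27 (adjusted p = 0.000816), or 0.0696 without Kupffer TG replicate 2. Hepatocyte markers had -2.78 (adjusted p = 0.00626), or 0.194 without Kupffer TG replicate 2 with the direction turned, 0.29 without Kupffer WT replicate 1, 0.109 without MoM TG replicate 1. Endothelial markers had -5.48 (adjusted p = 1.8e-07). Stellate cell and fibroblast markers had -3.53 (adjusted p = 0.00157), or 0.673 without Kupffer TG replicate 2, 0.0811 without MoM WT replicate 2. Cholangiocyte markers had -5.87 (adjusted p = 6.8e-06). Without both libraries rich in other cells' RNA, 8 of the 14 lists kept their call and direction. There, endothelial markers had adjusted p = 0.416, lipid-associated macrophage genes 0.221, dead cell clearance 0.341, hepatocyte markers 0.295 and stellate cell markers 0.188, and Kupffer cell identity turned upward (4.3e-06). With an estimated correlation all 14 had adjusted p = 0.612 to 0.772.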

How the results depend on the processing

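The counts of called genes moved with the tool and with single libraries, and the cause was not tested. In TG against WT Kupffer cells edgeR called 0 genes, with 0 to 257 when 1 library was left out; DESeq2 called 251, and 185 on only the 4 libraries. In TG against WT MoM edgeR called 0 with any library left out, and DESeq2 called 141, and 222 on only the 4 libraries. In WT MoM against Kupffer cells edgeR called 178, with 0 to 1434 when 1 library was left out, 2677 without both libraries rich in other cells' RNA, and 1585 on only the 4 libraries. DESeq2 called 2867 there, and 3905 on only the 4 libraries. In TG MoM against Kupffer cells edgeR called 381, with 0 to 1026 when 1 library was left out, 2130 without both libraries, and 0 on only the 4 libraries. DESeq2 called 2563 there, and 3552 on only the 4 libraries. For the interaction edgeR called 0, with 0 to 83 when 1 library was left out, and DESeq2 called 47. With the replicate number as a block the counts were 234 in WT and 301 in TG for MoM against Kupffer cells, and 0 elsewhere. With that block 23 lists were called in TG against WT Kupffer cells, 17 in MoM, 23 in WT and 22 in TG MoM against Kupffer cells, and 13 for the interaction, of which 23, 17, 23, 21 and 12 were also called without it. Deviations of same-numbered libraries from their group means correlated across genes at -0.055 for Kupffer and MoM WT, 0.578 for Kupffer and MoM TG, 0.258 for Kupffer WT and TG, 0.136 for MoM WT and TG, 0.208 for Kupffer WT and MoM TG, and 0.227 for Kupffer TG and MoM WT. The labels name no shared animal or batch, and the numbers were not taken to pair the samples. A gene to which DESeq2 gave no adjusted p stays without one. Where 1 library of a group was left out, the lone library left was assumed to vary like the other groups.

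With an estimated correlation between genes 0 lists were called in TG against WT Kupffer cells (23 with the preset), 0 in MoM (18), 0 in WT MoM against Kupffer cells (23), 0 in TG (23) and 0 for the interaction (14). Among lists called with the preset, the lowest adjusted p was 0.612 in each of the 5 comparisons, also between the macrophage subsets. That setting therefore set no list apart from the others, and its power was not tested. Among named genes, 194 results gave 2868 values under the alternatives, of which 2283 stayed the same, 371 were weaker, 196 stronger and 18 reversed.

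The reversed log2 fold changes followed the 2 libraries rich in other cells' RNA, except for Tgfbr2. In TG against WT Kupffer cells, Clec4g, a lectin of endothelial cells, ranged from -0.98 to 5.36 when 1 library was left out and had -0.98 without both libraries. Eng ranged from -0.26 to 4.97 and had -0.26 without both. Kit, a receptor of mast cells, ranged from -0.27 to 5.16 and had -0.27 without both. The lowest value of each came without Kupffer TG replicate 2. In TG against WT MoM, C1qa, a complement subunit, ranged from -3.31 to 0.46 and had 0.45 without both. Cd163 ranged from -5.25 to 0.24 and had 0.22 without both. Clec4f ranged from -5.40 to 1.36 and had 1.35 without both. Vsig4 ranged from -4.70 to 0.47 and had 0.44 without both. The highest value of each of these 4 came without MoM WT replicate 1. Tgfbr2 in MoM ranged from -0.18 without TG replicate 1 to 0.30 without WT replicate 1, with -0.12 without WT replicate 2. In the interaction, Marco ranged from -4.95 without MoM WT replicate 2 to 0.42 without MoM WT replicate 1, with -3.99 with all libraries and 0.034 without both.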

Other observations

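The genes here were chosen after the values were seen: the lowest library of 1 genotype stood at least 3 times above the highest of the other, with a mean of at least 50 CPM in the higher group. In Kupffer cells 16 genes met this with TG higher and 3 with TG lower. Other splits of the same 4 libraries gave 1 and 33 genes for replicate 1 against 2, and 0 and 0 for the crossed split, so TG against WT gave fewer genes in all than replicate 1 against 2. Among those higher in TG were Serpina3g, a protease inhibitor (1222 ± 264 CPM in TG and 165 ± 7.97 CPM in WT, n = 2), Acod1, which makes itaconate (165 ± 34.6 and 24.1 ± 2.01 CPM), Ptgs2, which makes prostaglandins (78.1 ± 4.19 and 13.1 ± 9.50 CPM), and Mmp14, a membrane metalloprotease (238 ± 53.2 and 51.0 ± 14.7 CPM). Lower in TG were Cd207, langerin (31.0 ± 17.1 and 275 ± 93.6 CPM), Kcnj16, a potassium channel (9.62 ± 3.13 and 79.3 ± 2.22 CPM), and Nid2, a basement membrane protein (24.9 ± 19.7 and 118 ± 0.735 CPM).

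Marco stood higher relative to Clec4f in both TG Kupffer libraries than in WT: the ratio of their CPM was 0.0599 for the WT Kupffer mean, 0.838 in TG replicate 1 and 1.21 in TG replicate 2. In MoM WT replicate 1, which carried Kupffer genes, it was 0.0958.

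In MoM, 4 genes met the rule with TG higher and 5 with TG lower, against 2 and 6 for replicate 1 against 2 and 0 and 0 for the crossed split. Gda, a guanine deaminase, was among those higher in TG in both subsets, with 331 ± 152 and 46.5 ± 17.7 CPM in MoM and 82.3 ± 20.4 and 4.95 ± 2.09 CPM in Kupffer cells (n = 2). Gas6, a bridge between dying cells and their receptors, was lower in TG MoM (17.0 ± 14.2 and 88.1 ± 8.94 CPM), and so was Xcr1 (8.82 ± 5.98 and 58.3 ± 9.52 CPM). The other 3 lower genes were the hepatocyte genes Alb, Serpina1a and Serpina1c. Gas6 also stood at 115 CPM in Kupffer TG replicate 2, the library rich in endothelial markers, against 22.1 to 36.7 CPM in the other Kupffer libraries. Across all tested genes the groups did not overlap in 16.7% with TG higher and 17.7% with TG lower in Kupffer cells. In MoM the shares were 19.2% with TG higher and 20.04% with TG lower, where chance gives 16.7% in each direction. Replicate 1 against 2 gave 16.3% and 21.3% in Kupffer cells, and 18.3% and 19.5% in MoM. The crossed split gave lower shares in each direction in both subsets. The excess over chance in MoM was therefore not particular to the genotype split.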
